A study of Caenorhabditis elegans with 4 samples.

How the data were processed

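Trimethylation of histone H3 at lysine 4 (H3K4me3), a modification known from promoters of transcribed genes, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in Caenorhabditis elegans. Per the labels, wild-type N2 worms at the third larval stage (L3) were grown in liquid culture, frozen, ground and crosslinked with 1% formaldehyde. The extract was sonicated, and the libraries were size selected and amplified by PCR. The labels describe 4 samples, of which 2 are H3K4me3 ChIP samples and 2 are input DNA samples. The peak lists of the ChIP samples were analysed. Data of the input DNA samples were not analysed here, although the labels name 1 input sample as the control of each ChIP sample.

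The submitters' processing notes name BWA, a read aligner, and its version and settings are not given in the sources used here. Per the file headers, the deposited peak positions are on the WormBase WS190 build of the genome. Each ChIP sample has its own deposited list, so peaks were called per sample and not on pooled reads. The caller is not given unambiguously, since the deposited lists carry the names of both MACS and MA2C, a pair of peak callers. The deposited lists hold other values, the start and end of each peak, and a score for each peak as the authors' peak caller gave it. The scale of this score is not named. The lowest scores lie just above 50, and many peaks are tied at exactly 3100, which was treated as a ceiling. The few peaks above 3100 were ranked as tied with those at the ceiling. Scores were used to describe, rank and band peaks within each list and to correlate the lists. Under Other observations, the same score cutoffs were set across both lists. Read depths, the caller's thresholds and any filters are not given in the sources used here. A missing peak is therefore not evidence that the mark was absent.

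Peaks of the 2 lists were called found in the other list when they overlapped one of its peaks by at least 1 bp. Overlapping peaks of the 2 lists were joined into regions, and a region holding peaks of both lists was called shared. The observed overlap was set against 1000 circular shifts of one list within each chromosome, with a one-sided permutation p. The span of a chromosome was taken as the end of its last peak in either list, a stand-in for its length, and the spans summed to 100.1 Mb. Densities on X and autosomes were compared by permuting 500 kb bins among chromosomes 100000 times, two-sided. Mean score percentiles and log2 widths were compared in the same way. The score percentile of a shared region is the mean of the percentiles of its highest peak in each list. For the comparison along chromosomes, each span was divided into 3 equal parts. The middle part is called the centre and the outer parts the arms, and bins were permuted between centre and arms within chromosomes. The difference of this ratio between X and autosomes was tested in another way. Densities were first scaled to the mean of X and to that of autosomes. X labels were then permuted among the bins of the centres and, apart from these, among the bins of the arms. Peaks found in one list alone were compared with the others by rank-biserial correlation and 100000 permutations of the peaks, two-sided. Shares were compared by Fisher's exact test, two-sided. Intervals of shares are 95% Wilson intervals, and those of ratios and differences are 95% bootstrap intervals from 2000 draws of bins. Intervals of correlations are 95% intervals across peaks or regions. Tests used a threshold of 0.05.

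Nothing in the labels says that the 2 ChIP samples came from separate cultures. The p-values therefore measure only the spread among peaks or bins within these samples, and the intervals cover only the counting error of peaks or, for bootstrap intervals, the spread among bins. The permutation and the bootstrap treat neighbouring bins as independent. Where neighbouring bins are alike, p-values may be too small and intervals too narrow. PCR-amplified reads without molecular identifiers are not independent molecules. No read counts were used, and the precision is set by the number of peaks in each list.

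The tests had been written down before the data were examined, with genes as the unit for X and for chromosome arms. The gene table at hand is for the WBcel235 build and holds no annotation of WS190, so no peak was assigned to a gene and no coordinates were carried between builds. The share of peaks at gene 5′ ends, the share of genes with a peak, and 25 gene lists were for that reason not tested. X and the arms were tested on shared regions and 500 kb bins instead of genes. The rule for named genes was carried over to regions. It took the 10 widest shared regions and, for each replicate, the 5 highest-scoring peaks found in that list alone. Its remaining part, the highest mean score rank, singled out no region because 593 shared regions were tied at the ceiling in both lists. The comparisons of scores and widths on X, of the X share between the lists, of peaks at equal score, and of single bins were added after the lists had been examined, as was naming the widest shared region of each chromosome.

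Alternatives fixed beforehand were the peaks at or above the median score of each list, the 3280 top-scoring peaks of each list, a reciprocal overlap of 50% of both peaks, peaks closer than 500 bp merged, summed scores per region, arms set as the parts outside the central 50% of each span, and each replicate left out. Also fixed beforehand were peaks with no peak of the other list within 500 bp, and regions with a single peak in each list. Alternatives added after the data were seen were bins of 250 kb and 1 Mb, omission of chromosome V, omission of regions at the score ceiling, and the number, width and covered length of the 3280 top-scoring peaks.

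The tests were tested on simulated data, in 40 sets of 3280 peaks each. A simulated log2 ratio of X to autosomal density of −0.415 was recovered with a mean of −0.39 and called in 40 of 40 sets. With no simulated effect, that ratio was called in 2 of 40 sets, the ratio of centre to arm density in 4, and the difference of that ratio between X and autosomes in 3. The last test also called 4 of 40 sets in which centres were denser by the same factor on every chromosome. A simulated difference of −10 percentage points in the share of X peaks found in the other list was called in 38 of 40 sets, and a difference of 0 in 3. Simulated peaks were placed independently of one another, at the same rate on every autosome. The real lists differed in density between autosomes. These simulations therefore do not show how often the bin tests call falsely on the real lists. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.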

Results

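H3K4me3 was profiled by ChIP-seq in whole L3 larvae of the wild-type C. elegans strain N2, in 2 replicates of a single group. The labels give no treatment, mutant or second stage, so the comparisons were those between the replicates, between chromosomes, and between parts of chromosomes. The peak list of replicate 1 held 4408 peaks with a median width of 1260 bp (interquartile range 933 to 1806 bp). The list of replicate 2 held 3280 peaks with a median width of 1377 bp (interquartile range 1031 to 1928 bp). Peaks covered 6.86 Mb in replicate 1 and 5.40 Mb in replicate 2, or 6.85% and 5.39% of the span of the 6 chromosomes. Replicate 1 thus had 1.34 times as many peaks and covered 1.27 times as many bases. The score, which is the authors' own value for each peak, had a median of 905.0 in replicate 1 and 684.0 in replicate 2. It reached its ceiling in 1314 peaks of replicate 1 (29.8%, 95% interval 28.5 to 31.2%) and in 595 peaks of replicate 2 (18.1%, 16.9 to 19.5%). Read depths are not known, so the numbers of peaks do not compare the amount of H3K4me3 in the samples. All positions are on the WS190 build, and no gene is assigned to them.

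The replicates marked largely the same sites. Of the 3280 peaks of replicate 2, 2996 were found in replicate 1 (91.3%, 95% interval 90.3 to 92.3%). Of the 4408 peaks of replicate 1, 2948 were found in replicate 2 (66.9%, 65.5 to 68.3%). Joined together, they formed 2917 shared regions with a median width of 1608 bp (interquartile range 1208 to 2297 bp). Circular shifts of the lists gave a mean overlap of 14.0% and at most 17.1% for the peaks of replicate 2, and a mean of 10.6% and at most 12.8% for those of replicate 1. The Jaccard index of covered bases was 0.618, against a mean of 0.0332 over shifts. Each of these 3 values had a one-sided permutation p of 0.000999, the smallest that 1000 shifts can give.

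Sites with high scores in one replicate had high scores in the other. Across the 2917 shared regions, Spearman's rho of the scores was 0.886 (95% interval 0.878 to 0.894) and Pearson's r of log10 scores was 0.827. Without the regions at the score ceiling in either list, rho was 0.786 over 1610 regions. Widths followed the same order, with a rho of 0.827 over 2818 regions that held a single peak in each list. In these, the peak was wider in replicate 1 in 65.0% of regions, although the median log2 ratio of widths was only 0.05. Over the regions of unequal width alone, the 95% interval of this share was 63.4 to 66.9%. Wider peaks also had higher scores within each list, with rho of 0.706 in replicate 1 and 0.584 in replicate 2. Peak counts in 500 kb bins correlated between the replicates with Pearson's r of 0.893 and rho of 0.883 over 197 whole bins. These correlations are across regions or bins of 2 samples, and such units are not independent replicates.

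Shared regions wider than 5 kb were present on every chromosome. There were 65 of them, and 5 lay on X. These widths are those of the joined peaks of both lists, so a region can be broad in 1 list alone. The widest was on chromosome V (20660071 to 20673849, 13779 bp), and replicate 1 covered all of it with a peak at the ceiling. Replicate 2 covered 4609 bp of the same region, with a score of 105.8. The next widest, on chromosome II (13816910 to 13828879, 11970 bp), was at the ceiling in both lists and was called as 1 peak in replicate 1 and as 3 peaks in replicate 2. Chromosome II held another 3 of the 10 widest regions, at 10541352 to 10550250 (8899 bp), 8124291 to 8132030 (7740 bp) and 7677151 to 7684771 (7621 bp). All of them were at the ceiling in replicate 1 and scored 2335, 2179 and 2088 in replicate 2. Another 3 were at the ceiling in both lists, on chromosome I at 7079719 to 7088560 (8842 bp), on chromosome V at 9543222 to 9550910 (7689 bp) and on chromosome III at 3862415 to 3869952 (7538 bp). A region on chromosome III at 10812571 to 10820170 (7600 bp) scored 1821 in replicate 2, and one on chromosome I at 5874629 to 5882372 (7744 bp) scored only 79.9 there. The widest shared region of chromosome IV (11116866 to 11123443, 6578 bp) was at the ceiling in both lists. That of X (2211950 to 2219150, 7201 bp) was at the ceiling in replicate 1, whereas replicate 2 had a peak of 923 bp there with a score of 50.1.

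Peaks found in a single list were mostly weak and narrow. The 1460 peaks found in replicate 1 alone had a median score of 129.6, against 2520 for its peaks found in both lists, and median widths of 871 and 1505 bp. The 284 peaks found in replicate 2 alone had a median score of 80.8, against 880.1 for the others, and median widths of 1088 and 1407 bp. Scores under 300 made up 82.6% of the former and 87.3% of the latter. The rank-biserial correlations for score were −0.891 in replicate 1 and −0.737 in replicate 2, and those for width were −0.644 and −0.297. All 4 had a two-sided permutation p of 1e-05, the smallest that 100000 permutations can give. The share of replicate 1 peaks found in replicate 2 went from 9.26% at scores under 100 and 24.0% at 100 to 300 to 71.1% at 300 to 1000, 97.3% from 1000 to the ceiling, and 99.6% at the ceiling. The corresponding shares of replicate 2 peaks were 67.9%, 87.3%, 95.5%, 99.5% and 100%.

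**Figure D1:**
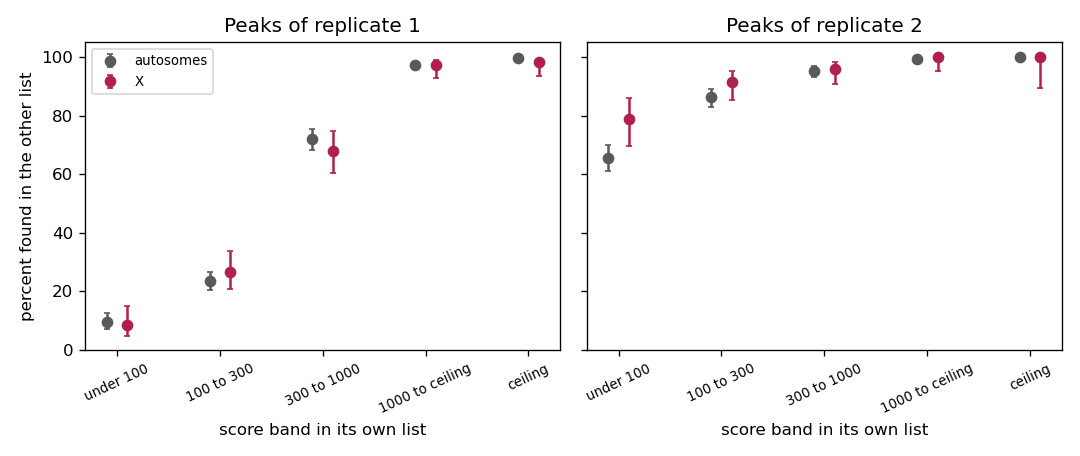
Share of peaks (percent) found in the other list, by score band in their own list (peaks scoring under 100, 100 to 300, 300 to 1000, 1000 to the ceiling, and at the ceiling), for replicate 1 on the left and replicate 2 on the right, with autosomal peaks in grey and X peaks in red. Bars are 95% Wilson intervals; for all chromosomes together the share went from 9.26% to 99.6% in replicate 1 and from 67.9% to 100% in replicate 2.

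A few strong peaks were found in a single list. In replicate 1, 5 peaks at or above the ceiling had no overlapping peak in replicate 2, and the broadest was on chromosome I (8975407 to 8987482, 12076 bp), 4455 bp from the nearest peak of replicate 2. The others were on chromosome IV (14093025 to 14096540, 3516 bp, and 3368291 to 3371335, 3045 bp) and on X (14577682 to 14580978, 3297 bp, and 5148806 to 5150653, 1848 bp). In replicate 2, no such peak reached the ceiling, and the highest score was 2851 on chromosome I (573066 to 575473), 33890 bp from the nearest peak of replicate 1. The next were on chromosome IV at 4515002 to 4517651 with a score of 1369 and at 1817804 to 1819326 with a score of 1266. They were followed by chromosome III at 12992287 to 12993869, with a score of 1082, and chromosome V at 1164830 to 1165857, with a score of 905.3.

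Peak density differed between chromosomes and along them. Chromosomes III and I were the densest, with 40.4 and 39.3 shared regions per Mb, followed by II with 31, IV with 26.4, X with 22.8 and V with 20.7. Chromosome V was also the sparsest in each list, with 31.3 peaks per Mb in replicate 1 and 24.7 in replicate 2. Among whole 500 kb bins, the highest density of shared regions was on chromosome III at 9500001 to 10000000, with 70 per Mb. The bin on chromosome V at 17000001 to 17500000 held no peak in either list.

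**Figure D2:**
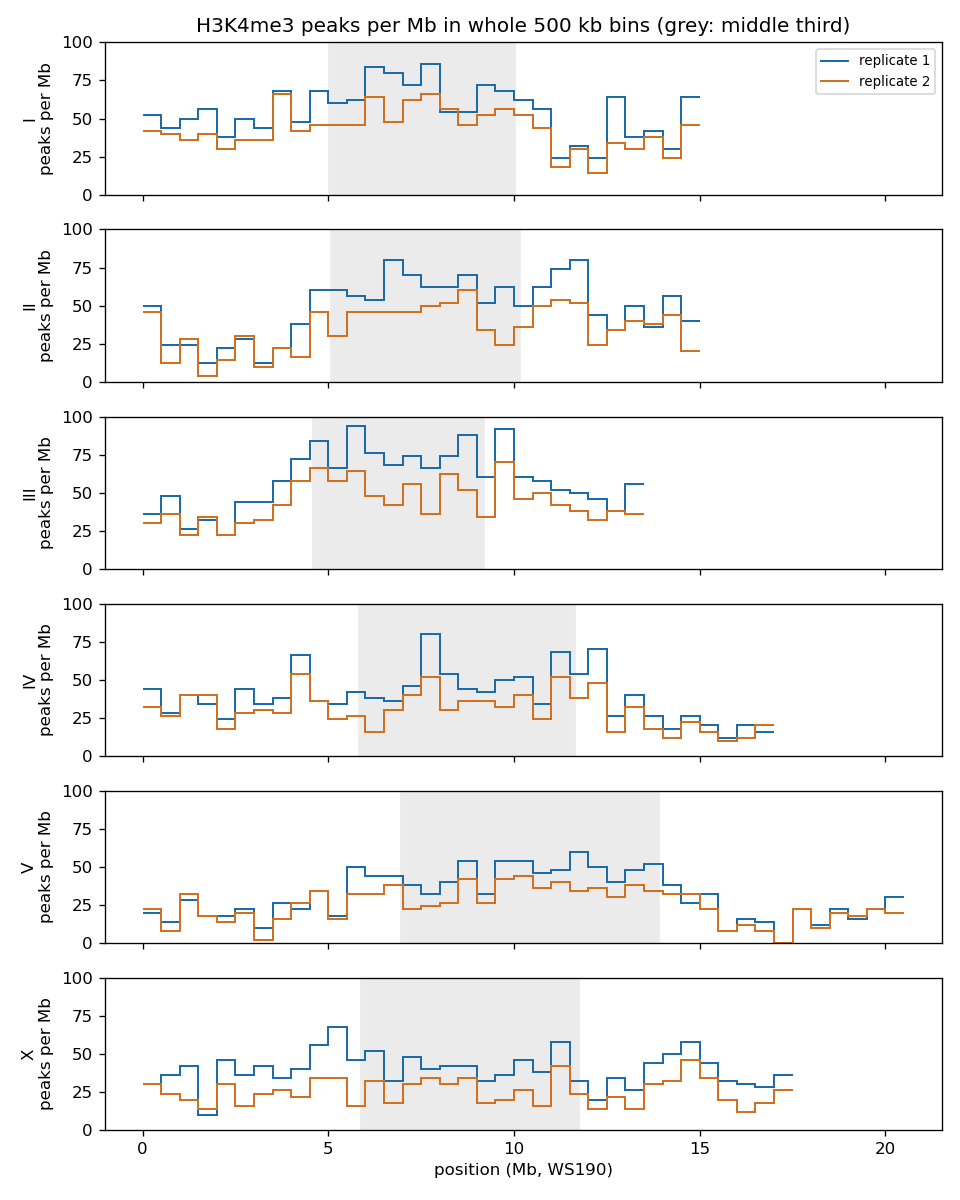
Peaks per Mb (vertical axis) in whole 500 kb bins along the 6 chromosomes (horizontal axis, position in Mb on WS190), with replicate 1 in blue and replicate 2 in orange; the grey area is the centre of each chromosome. The lines of the replicates follow each other (Pearson's r 0.893 over these 197 bins), and chromosome V has a bin with 0 peaks per Mb in both.

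The X chromosome, which in this organism is subject to dosage compensation, carried fewer shared H3K4me3 regions per Mb than the autosomes together. There were 402 shared regions on X (22.8 per Mb) and 2515 on autosomes (30.5 per Mb), a ratio of 0.747 (95% bootstrap interval 0.649 to 0.858). The permutation of bins gave a two-sided p of 0.00109. In the whole list of replicate 2 the ratio was 0.732 (0.646 to 0.832, permutation p = 0.00012). In the whole list of replicate 1 it was 0.881 (0.785 to 0.986) and did not pass the test (permutation p = 0.107), so the call did not hold without replicate 2. Shared regions hold 91.3% of the peaks of replicate 2, so the ratios of 0.747 and 0.732 are not separate support. Of the peaks of replicate 1, 58.2% on X and 68.5% on autosomes were found in replicate 2. Within score bands the difference was −0.451 percentage points (two-sided permutation p = 0.75). Fewer shared regions on X therefore do not by themselves show fewer marked sites, since weaker X peaks may be missing from replicate 2. Among shared regions of the peaks at or above the median score of each list (136 on X, 1451 on autosomes), the ratio was 0.438 (0.360 to 0.525, permutation p = 1e-05). X peaks had lower scores in both lists, so this filter leaves out more of them. The ratio of 0.438 is therefore no separate support for a lower density on X. With whole chromosomes as the unit, X lay within the spread of the autosomes (31.6 ± 8.43 shared regions per Mb, SD, n = 5), above chromosome V with 20.7 (exact one-sided p = 0.333). Genes were not counted, so these densities are not corrected for the number of genes per Mb.

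H3K4me3 peaks on X had lower scores and were narrower than those on autosomes in both replicates. The median score on X was 470.8 in replicate 1, against 932.2 to 1314 on single autosomes, and 323.0 in replicate 2, against 588.7 to 973.7. The ceiling was reached by 15.5% of X peaks and 29.6 to 34.0% of the peaks of single autosomes in replicate 1, and by 7.21% and 14.9 to 22.7% in replicate 2. Both replicates were at the ceiling in 32 of the 402 shared regions on X (7.96%), against 17.9 to 24.6% on single autosomes. Shared regions on X had a median width of 1405.5 bp, against a mean of medians of 1643 ± 67.1 bp (SD, n = 5 autosomes). The mean score percentile of shared regions was 49.6 on X and 61.1 on autosomes, a difference of −11.5 (95% bootstrap interval −13.7 to −9.0). Differences in replicates 1 and 2 were −9.76 (−12 to −7.55) and −12.5 (−14.9 to −9.91). Widths on X were 0.872 times those on autosomes in shared regions (0.833 to 0.910), 0.896 times in replicate 1 (0.862 to 0.930) and 0.867 times in replicate 2 (0.830 to 0.903). These 6 comparisons had permutation p-values of 1e-05 (2e-05 for width in replicate 1), and adjusted p-values by the method of Benjamini and Hochberg of 1.2e-05 (2e-05 for that width). The 6 are not separate support, since shared regions are made of peaks of both lists and wider peaks had higher scores. With whole chromosomes as the unit, X was the lowest of 6 in median score and median width in both lists, and an exact test of X against 5 autosomes cannot go below a one-sided p of 0.167.

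On autosomes, there were more H3K4me3 regions per Mb in the centres than in the arms, without correction for gene density. The ratio of centre to arm density in shared regions was 1.55 (95% bootstrap interval 1.38 to 1.76, two-sided permutation p = 1e-05). It was 1.88 on chromosome V, 1.56 on II, 1.49 on I, and 1.43 on both III and IV. On X the ratio was 1.18 (0.942 to 1.49) and did not pass the test (permutation p = 0.212). It was the lowest of the 6 chromosomes in shared regions and in each list, with 1.09 in replicate 1 and 1.12 in replicate 2. The difference between X and autosomes itself, −0.40 on the log2 scale, did not pass the test (permutation p = 0.0636). In the whole list of replicate 1 it was −0.54 and passed (permutation p = 0.00522), and in the whole list of replicate 2 it was −0.35 (p = 0.0779).

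**Figure D3:**
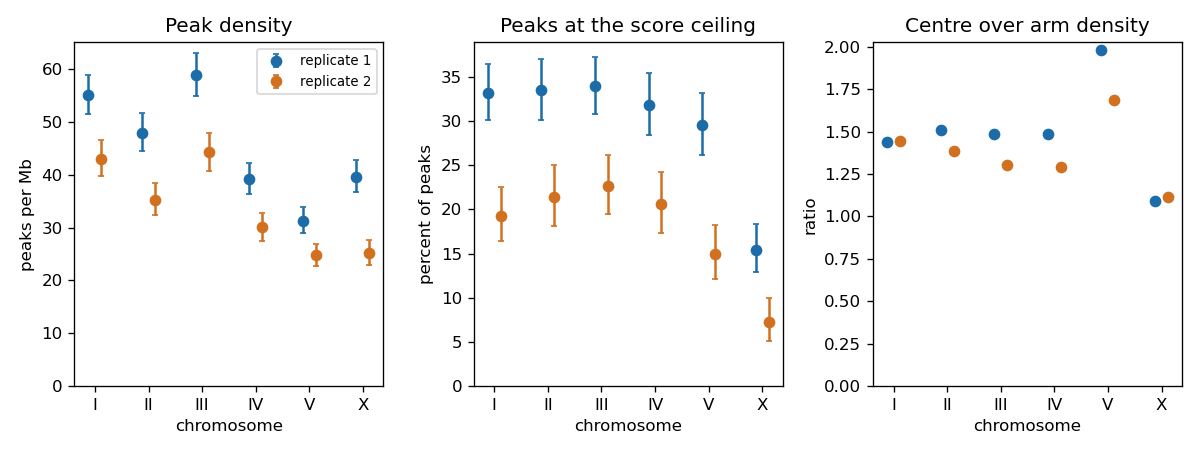
Peaks per Mb with 95% exact Poisson intervals (left), percent of peaks at the score ceiling with 95% Wilson intervals (middle), and ratio of centre to arm density (right, no interval drawn) for chromosomes I to V and X, with replicate 1 in blue and replicate 2 in orange. X has the lowest share at the ceiling (15.5% and 7.21%) and the lowest ratio (1.09 and 1.12) in both replicates, while chromosome V has the lowest density.

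The lists differed in how much of each lay on X. X held 699 of the peaks of replicate 1 (15.9%) and 444 of those of replicate 2 (13.5%), an odds ratio of 1.2 (Fisher's exact test, p = 0.0048). Against the 3280 top-scoring peaks of replicate 1, of which 480 lay on X (14.6%), the difference was 1.1 instead of 2.32 percentage points and did not pass (Fisher's exact test, p = 0.214). Among peaks found in one list alone, X held 292 of 1460 in replicate 1 (20.0%) and 35 of 284 in replicate 2 (12.3%), an odds ratio of 1.78 (Fisher's exact test, p = 0.00205). Fewer X peaks than autosomal peaks of replicate 1 were found in replicate 2, 58.2% (54.5 to 61.8%) against 68.5% (67 to 70%), a difference of −10.3 percentage points (Fisher's exact test, p = 1.76e-07). Compared within the 5 score bands, the difference was −0.451 percentage points and did not pass the permutation test (two-sided p = 0.75). Of the peaks of replicate 2, 92.1% on X and 91.2% on autosomes were found in replicate 1 (Fisher's exact test, p = 0.587). Within score bands, X peaks of replicate 2 were found more often, by 4.55 percentage points (two-sided permutation p = 0.00378). Most peaks of the lists lay at the same sites. Fisher's exact test on the lists ignores this, so its p-values of 0.0048 and 0.214 do not decide whether the X shares differ. The difference in X share rests on the peaks found in one list alone. The part of these that belonged to replicate 1 was larger on X than on autosomes, by 6.87 percentage points (two-sided permutation of 500 kb bins, p = 0.0394). When both lists held 3280 peaks, X held 21.4% and 14.7% of the peaks found in one list alone (odds ratio 1.58, Fisher's exact test p = 0.00978). The part that belonged to replicate 1 was then larger on X by 11.2 percentage points (permutation of bins, p = 0.0547). With peaks closer than 500 bp merged and lists of 3117, it was larger by 11.8 percentage points (permutation of bins, p = 0.0431). No p-value of these comparisons was adjusted for their number.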

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

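Alternatives chosen after the data were seen were other bin sizes, omission of chromosome V, omission of regions at the score ceiling, and the description of the 3280 top-scoring peaks. Of 67 alternative values for 16 results, 53 kept their direction and their side of the threshold or, where no test applied, stayed within 1.5 times (peak numbers), 1 SD between the replicates (widths and lengths) or the 95% interval (rho), and 0 reversed direction. Among those, the share of peaks found in the other list ranged from 63.3 to 85.2% in replicate 1 and from 85.1 to 97.9% in replicate 2, and the log2 ratio of centre to arm density on autosomes from 0.51 to 0.70. Spearman's rho of scores moved to 0.898 with a reciprocal overlap and to 0.786 without regions at the ceiling. With either replicate left out, the log2 ratio of X to autosomal density ranged from −0.45 to −0.18, and the test no longer passed without replicate 2. With either replicate left out, the difference in log2 centre to arm ratio between X and autosomes ranged from −0.54 to −0.35 and passed without replicate 2. It also passed with the top-scoring peaks (−0.45), with arms outside the central 50% (−0.55) and with bins of 250 kb (−0.37), but not with bins of 1 Mb (−0.36, permutation p = 0.175), peaks at or above the median score (−0.51, permutation p = 0.0502) or without chromosome V (−0.35, permutation p = 0.0745). It thus passed in 4 of 8 alternatives, and the cause was not tested. Peaks at or above the median score number 2204 and 1640 by construction and cover 4.41 and 3.27 Mb, with median widths of 1658 and 1684 bp. The 3280 top-scoring peaks of replicate 1 had a median width of 1495 bp. Gene windows of other widths, isolated genes and the other alternatives for gene results were not run, since no peak was assigned to a gene. Read depth is not known, so its effect on the weak peaks of either list was not measured.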

Other observations

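The tests chosen only after their results were seen were those of the shorter list, of weak sites, of broad regions and of scattered losses, the comparison of X with autosomes among the ceiling regions, and the count of neighbouring losses. Outside the extremes already given, the densest whole 500 kb bin held 60 shared regions per Mb on chromosome I (7500001 to 8000000), 58 on II (8500001 to 9000000), 52 on IV (7500001 to 8000000) and 42 on V (8500001 to 9000000). On X it held 44 and lay in the right arm (14500001 to 15000000). After the empty bin on chromosome V, the sparsest whole bins were on V (3000001 to 3500000, 2 per Mb) and on II (1500001 to 2000000, 4 per Mb, and 3000001 to 3500000, 6 per Mb). The widest peak found in replicate 2 alone was on X (108845 to 114611, 5767 bp) and had a score of 362.7.

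The first pattern is the lower score of shared regions on X. Narrower peaks are not the whole cause, since with the mean of each of 10 width classes removed X stayed lower, with a difference of −7.90 percentile points (permutation p = 1e-05, the smallest the permutations can give), against −11.5 before. A few segments of X are not the cause either, since 32 of 36 bins of X (88.9%) lay below the median autosomal bin, with a median of 49.9 on X and 62.4 on autosomes. Sequence composition, repeats and the coverage of the input DNA were not tested and stay open. The design has a single group, so no biological explanation was tested.

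The second pattern is the larger share of X in replicate 1, most of all among the peaks found there alone. Over all chromosomes, most of these peaks are not edges of sites called in replicate 2. Only 11.4% of them (166 of 1460) lay within 1 kb of a peak of that replicate, although shifted peaks gave fewer (6.40%, one-sided permutation p = 0.000999). Those on X were not tested apart. A lower score of X peaks may account for their loss in replicate 2, since within score bands of replicate 1 their share found differed from that of autosomal peaks by −0.451 percentage points (permutation p = 0.75), against −10.3 without bands, but it leaves open why X peaks of replicate 2 were found more often at equal score (by 4.55 percentage points). Whether the shorter list of replicate 2 accounts for the X share cannot be told apart from other causes. With both lists at 3280 peaks, X held 14.6% of replicate 1 and 13.5% of replicate 2 (Fisher's exact test, p = 0.214). That test ignores that most of these peaks lay at the same sites, so it does not decide the question. X held 21.4% of the 485 peaks of replicate 1 alone and 14.7% of the 421 of replicate 2 alone. For the latter, Fisher's exact test passed (p = 0.00978) but the two-sided permutation of bins did not (p = 0.0547; p = 0.0431 with peaks closer than 500 bp merged), and no biological explanation was tested.

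The third pattern is a set of 26 of 1312 ceiling regions of replicate 1 (1.98%) that scored under 300 in replicate 2 (21) or had no peak there (5), while 0 of 593 ceiling regions of replicate 2 did so in replicate 1. The ceiling held 29.8% of the peaks of replicate 1 and 18.1% of those of replicate 2, so the same cutoffs fall at unlike ranks. No comparison at equal rank was run, so 26 against 0 does not by itself show an asymmetry between the replicates. Peak borders placed slightly apart do not account for the 5 without a peak, since 100% of them lay over 500 bp from any peak of replicate 2. The 26 were wider, with a median of 3377 bp against 1978.5 bp (rank-biserial 0.551), and since the set was noticed among wide regions, the 18 not named in the report were tested apart, with a rank-biserial of 0.486 (permutation p = 0.00023), so that a candidate explanation is that broad regions differ more between the lists than narrow sites. With pieces closer than 500 bp joined, 23 of 1289 sites were left, and the 15 not named were again wider (rank-biserial 0.538, permutation p = 0.00021). These 15 come from the same 18 regions, so their width is not separate evidence. It goes against losses equally likely at sites of every width, on a test chosen after its result was seen. The clustering of the 23 did not pass the test (2 with another within 10 kb, against a mean of 0.136 in random draws, permutation p = 0.0656). Scattered losses are therefore not excluded. X held 7 of the 23 (30.4%) and 98 of the other 1266 (7.74%, Fisher's exact test, p = 0.0016), and whether the cultures differed was not tested.

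A further hypothesis was that shared regions lie in clumps beyond the gradient from arms to centres. Over whole chromosomes, the variance to mean ratio of counts in 100 kb bins was 1.47, against a mean of 1.08 for random placement within each chromosome (one-sided permutation p = 0.000999, the smallest 1000 placements can give). In the centres alone, where the contrast with the arms is left out, it was 1.21 against 1.08 (permutation p = 0.037, highest random value 1.37), so the excess was smaller there. Clumping within the arms was not tested, so the smaller excess cannot be credited to the gradient. Some clumping beyond the gradient may remain at this scale, on a test that passed narrowly. On X the ratio was 1.19 against 0.924 over the whole chromosome (permutation p = 0.005) and 0.910 against 0.915 in the centre (permutation p = 0.477), and the difference between X and autosomes was not tested.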
